A study of Homo sapiens with 6 samples.

How the data were processed

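The series holds 6 libraries of A549 cells, 3 with a hairpin against firefly luciferase (control) and 3 with a hairpin against BCLAF1 (BCLAF1-depleted). Groups and replicate numbers were taken from the labels. Sample names there write "si", whereas the treatment protocol describes short hairpin RNA delivered by lentivirus, and the protocol was followed. Per the labels' protocols, RNA was extracted with TRIzol and treated with DNase, polyadenylated RNA was selected with oligo(dT) beads, and directional libraries were made from fragmented RNA with random-primed reverse transcription. Selection by oligo(dT) makes levels depend on intact transcripts and on a poly(A) tail, so transcripts without one are measured in part.

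The deposited table of read counts gives whole-number counts per gene and library, not normalized, for 29122 genes. Per the submitters' processing notes, bcl2fastq, TopHat2 and edgeR were used with genome build GRCh38; their versions and roles, the counting tool, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, reads of genes that overlap on opposite strands cannot be assigned with certainty. The authors also deposited FPKM values for 28878 genes, which are fragments normalized for gene length and library size, and which were used here in alternatives and in 1 result of the closing section. No further normalization or filter is recorded in the labels. Each library has its own column, so replicates were not pooled, and all columns of per-sample values were used.

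Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood fit (glmQLFit and glmQLFTest) on the 3 control and 3 BCLAF1-depleted libraries with group as the only term and TMM scaling. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15907 genes. P-values were adjusted by Benjamini-Hochberg over these genes and called under 0.05. The SE of a log2 fold change is its size divided by the root of its F value. The common biological coefficient of variation was 15.3%. CPM values are scaled by TMM over the tested genes. Library totals ranged from 33409158 to 43928927 counts, and 3 counts, the floor used for a count of 0, equal 0.0683 to 0.0898 CPM. These floors use library totals without the TMM factors, so gene levels are set against them only roughly. They cover counting error only, as the reads carry no molecular identifiers.

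Before the data were examined, 34 gene lists were written from general knowledge of the pathways and of cell types that cultures could hold. The 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. The test was repeated with the correlation estimated for each list, and with fry, which asks only whether a list's own genes move one way. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list. Lists share some genes, and shared genes count in each. Genes were named by a rule also written before the data were examined: BCLAF1, MED23 and THRAP3 always, then the 10 largest higher and 10 largest lower log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, then up to 4 members past the threshold per list with the largest change, or the 2 with the highest mean CPM where none passed. The rule named 140 distinct genes, of which the text leaves out some, and single results of a few genes are not reported here. Names outside it are said to have been chosen after their values were seen, in the report beside them and in the closing section for all members of lists chosen later.

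Gene positions, exon lengths and GC content came from GENCODE release 29 on GRCh38, matched by identifier for 28362 genes, and 15775 tested genes (99.2%) had a length and GC value. Whether this release is the one behind the counts is not given in the sources used here. Length is the union of a gene's exons. The trend correction fitted, per library, a smooth function (mgcv 1.9.3, basis size 8) of length and GC content and used it as an offset in the same edgeR fit.

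The alternatives fixed before the data were examined were other scalings (DESeq2 size factors, upper quartile, library totals alone), no low-count filter or a stricter one of 5 CPM in at least 3 libraries, the replicate number as a block, each library left out in turn, the GC and length correction without and with the block, the DESeq2 1.42.0 Wald test, edgeR's exact test, limma-voom, limma-trend on the deposited FPKM as log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, and the other list tests. The GC and length correction without each BCLAF1-depleted library was added after seeing the data. All 205 genes recomputed under these settings include every gene whose values the text prints from the fit.

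The scripts were tested on simulated counts for this comparison, drawn for 15642 genes from the means and sizes of these libraries with 200 genes changed. Of the changed genes, 21.2% of those changed 1.5-fold, 75.4% of those changed 2-fold and 98.5% of those changed 4-fold were recovered. False calls numbered 8 of 136 (5.88%). Both groups were drawn with the same dispersion per gene. In the data the BCLAF1-depleted libraries differed more among themselves (Pearson correlations of log2 CPM 0.9802 to 0.9845) than the controls (0.9938 to 0.9951). These rates therefore do not show how often genes are called falsely when the spread differs by group. Of 33 lists 1 was called, which was the one made to move. Simulated genes were drawn independently of each other, whereas ribosomal protein genes had an estimated correlation of 0.58 in the data. The simulation therefore does not show how often the list test calls lists of correlated genes falsely. In the data a larger share of tested genes was called (35.8%), which loosens the adjusted threshold, so recovery can be higher than these rates. At this depth and number of replicates a missed call below 2-fold still does not show that a gene was the same in both groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.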

Results

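The libraries measured polyadenylated RNA of A549 cells, a human lung carcinoma epithelial line, by strand-directional RNA sequencing. BCLAF1, a nuclear protein tied to transcription and RNA processing, was targeted with a stably transduced lentiviral short hairpin RNA. Control cells carried a hairpin against firefly luciferase, a gene human cells lack. There were 3 control and 3 BCLAF1-depleted libraries, and the series title places them in a study of the Mediator subunit MED23, premature senescence and autophagy flux. The comparison asks which transcripts differ once BCLAF1 is lowered. Read counts summed to 41098232, 41019185 and 43928927 in control replicates 1 to 3, and to 33409158, 36355856 and 40820922 in BCLAF1-depleted replicates 1 to 3. At these depths 3 counts, taken as the floor for counting error only, equal 0.0683 to 0.0898 CPM per library before TMM scaling. CPM are counts scaled to a common library size. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. That spread was unequal: Pearson correlations of log2 CPM were 0.9938 to 0.9951 between controls and 0.9802 to 0.9845 between BCLAF1-depleted libraries. The fit takes 1 dispersion per gene for both groups, so its p-values do not allow for the wider spread of the BCLAF1-depleted libraries separately. Levels below are CPM, as mean ± SD (n = 3), and log2 fold changes are BCLAF1-depleted over control ± SE, with edgeR quasi-likelihood adjusted p-values.

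The 2 groups of libraries also differed in their make-up. Ribosomal protein genes took 5.70, 5.69 and 5.85% of counts in the control libraries and 7.14, 9.53 and 7.5% in the BCLAF1-depleted libraries. The nuclear non-coding RNA MALAT1 took 0.940, 0.945 and 0.983% in controls against 1.49, 2.12 and 2.19% after depletion. Mitochondrially encoded transcripts took 10.7, 11 and 11.1% in controls, 11.4 and 10.5% in BCLAF1-depleted replicates 1 and 2, and 19.3% in replicate 3. Fold changes followed transcript length: the median log2 fold change was 0.346 in the quintile of genes with the shortest exon length and -0.188 in the longest quintile. In the shortest quintile 901 genes were higher and 167 lower, and in the longest quintile 325 were higher and 950 lower. The slope was present in every BCLAF1-depleted library (shortest quintile 0.184, 0.447 and 0.348, longest quintile -0.109, -0.284 and -0.217), while the control libraries stayed between -0.016 and 0.020. Lists whose camera call changed once this trend and that with GC content were removed are given below with both values. Where a fry call printed in this report part was lost with the trend removed, that value is given too.

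**Figure D1:**
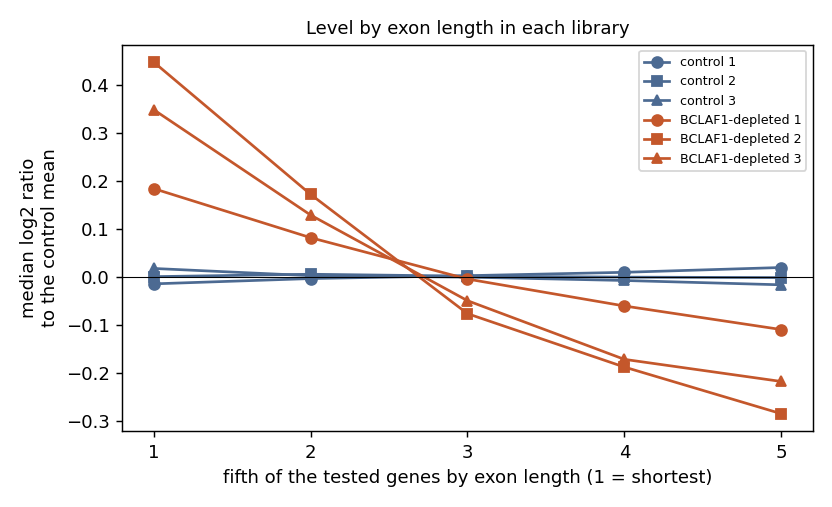
Median log2 ratio of each library to the control mean (y axis) in quintiles of the tested genes ordered by exon length (x axis, 1 the shortest); each line is 1 library, blue for control and orange for BCLAF1-depleted. The 3 BCLAF1-depleted lines fall from 0.184, 0.447 and 0.348 to -0.109, -0.284 and -0.217, and the control lines stay between -0.016 and 0.020.

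BCLAF1 itself was lower in every BCLAF1-depleted library. Its level was 211.1, 199.0 and 203.2 CPM in control replicates 1 to 3 and 39.0, 35.7 and 53.1 CPM in BCLAF1-depleted replicates 1 to 3 (204.4 ± 6.13 against 42.6 ± 9.23 CPM). The log2 fold change was -2.26 ± 0.16 (adjusted p = 2.31e-05), a 4.8-fold lower level. BCLAF1 (ENSG00000029363.14) is a protein-coding gene on the minus strand of chromosome 6, from 136256627 to 136289851 in GRCh38. How reads shared with pseudogene copies of it were counted is not given in the sources used here. MED23 (ENSG00000112282.16; chromosome 6, 131573966 to 131628229, minus strand), which codes for a subunit of the Mediator tail, had 6.98 ± 1.17 CPM in controls and 4.74 ± 1.75 CPM after depletion. Its log2 fold change of -0.56 ± 0.24 did not pass the threshold (adjusted p = 0.0955). MED23 passed without BCLAF1-depleted replicate 1 (-0.93, adjusted p = 0.00306), also with the GC and length trend removed there (-0.59, adjusted p = 0.0254). It also passed with no low-count filter (-0.60, adjusted p = 0.00824) and with the replicate number as a block (-0.60, adjusted p = 0.0456). THRAP3 (ENSG00000054118.12; chromosome 1, 36224416 to 36305357, plus strand), a protein related to BCLAF1, had 347.9 ± 22.5 and 376.1 ± 47.6 CPM. Its difference was smaller than the spread between replicates (0.11 ± 0.14, adjusted p = 0.562), and its sign turned with library totals as the only scaling.

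**Figure D2:**
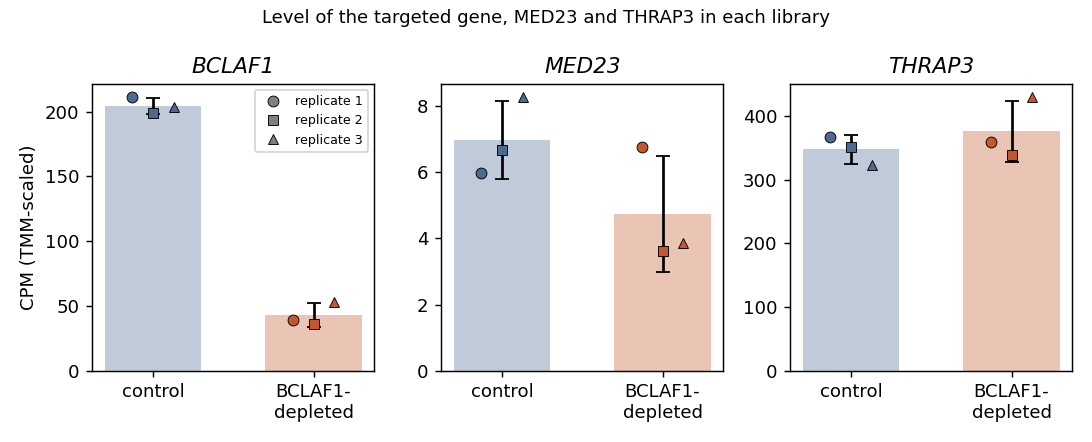
Level of BCLAF1, MED23 and THRAP3 in TMM-scaled CPM (y axes, from 0) in control and BCLAF1-depleted cells; points are single libraries, bars the group means and error bars the SD (n = 3). BCLAF1 was 35.7 to 53.1 CPM in the BCLAF1-depleted libraries and 199.0 to 211.1 CPM in the controls, while the groups overlapped for MED23 and THRAP3.

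Depletion of BCLAF1 went with changes across much of the transcriptome. Of 15907 tested genes, 2827 were higher and 2870 lower in BCLAF1-depleted cells at an adjusted p under 0.05, together 35.8%. Counts of called genes within a list are to be read against this share, which holds only for the fit of all 6 libraries. List counts in another setting are to be read against all calls of that setting. Without BCLAF1-depleted replicate 1, 3741 genes were higher and 4195 lower of 16277 tested. Without control replicate 2, these were 1383 and 1555 of 16257. With all 6 libraries, at least 2-fold changes were found for 962 higher and 817 lower genes. The higher genes included 2295 protein-coding genes and 532 of other types, the lower genes 2720 and 150. The first principal component held 68.3% of the variance and separated the groups. On it BCLAF1-depleted replicate 1 lay at 19.4, between the controls (-43.6, -42.4 and -40.9) and replicates 2 and 3 (54.2 and 53.4). Its BCLAF1 level, 39.0 CPM, lay between theirs (35.7 and 53.1 CPM). The second component held 13.4% and set BCLAF1-depleted replicate 3 apart from replicates 1 and 2. The values of the groups did not overlap for 8254 tested genes (51.9%, where chance gives 10%) and for 5590 of the called genes. Among the libraries left out in turn, a control lowered the counts most, to 1399 higher and 1549 lower without replicate 1, to 1383 and 1555 without replicate 2, and to 1519 and 1669 without replicate 3. With library totals as the only scaling the split was 1283 higher to 3662 lower, and the median of all tested genes was -0.21. With that scaling the rises of HMGA2, HMGA1, CLSPN, FANCF, SQSTM1, ATG12, GABARAP, AKT1S1, MED18, MED11, DGAT2, PPARG, CPT2, PCBP2, HSPA8, HSPA1A, HSPA1B, SFTPD and ITGAM, described below, were no longer past the threshold (adjusted p 0.0515 to 0.483). Once the GC and length trend was removed, ATG2B (-0.46), PRKAA2 (-0.47), HMGA1 (0.40), MED18 (0.47), SDF2L1 (0.43), HSPA1B (0.36), NDUFA1 (0.46) and NDUFS1 (-0.36) stayed past it at a smaller size, and CPT2 at a larger one (0.71). Calls were also lost with no low-count filter by PCBP2, CPT2, FANCF and SFTPD (adjusted p 0.055 to 0.127), with upper-quartile scaling by UQCRC1 (0.0643) and DNAJB1 (0.056), with limma-voom by PPARG (0.0517) and GABARAP (0.0515), and with the DESeq2 Wald test by SFTPD (0.0853). On the deposited FPKM values, the rises of HMGA2, HMGA1, CLSPN, FANCF, SQSTM1, ATG12, GABARAP, AKT1S1, SESN2, MED31, MED18, MED11, DGAT2, PPARG, CPT2, NDUFB9, MT-ND1, MT-ND3, RBM25, SRSF11, PCBP2, DNAJB11, HSPA8, HSPA1A, HSPA1B, CDH5, ITGAM and NEFM were not past the threshold in any of the 3 settings tried (adjusted p 0.0517 to 0.657), nor that of SFTPD in 2 (0.0631 and 0.126). With log2(FPKM + 1) and no filter, TP53I3, BAX, TOPBP1, ATG2B, CTSH, MITF, LAMP2, SCARB2, MED19, TM7SF2, COX6C, NDUFA1, RPLP1, MT-ND6, U2AF1L4, HNRNPH2, PTBP1, BCL2L11, DDIT3, SDF2L1, SEC24D, DNAJB1, CLDN1, CAV1 and PECAM1 lost theirs as well (0.0511 to 0.112). LMNB1 passed with log2(FPKM + 1) and log2(FPKM + 0.1) (both 0.0161), and MAP1LC3B in all 3 (0.0396 to 0.0464).

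Scaling by library totals alone also moved the lists described below. Of lists past the threshold, p53 targets then had 6 higher and 2 lower genes (median 0.06), NRF2 targets 6 and 2 (0.01), G1/S genes 1 and 19 (-0.41), DNA repair genes 0 and 17 (-0.48) and fatty acid genes 1 and 16 (-0.63). Higher genes numbered 14 of the interferon list (median 0.37), 9 of the oxidative phosphorylation list (0.25), 25 of the ribosomal list and 3 of the histone list (0.14). The medians were 0.13 for the secretory list and 0.43 for mitochondrially encoded genes. Of the other lists, higher and lower genes numbered 1 and 4 for senescence markers, 1 and 12 for autophagy, 1 and 6 for lysosome, 1 and 12 for mTOR and AMPK, 2 and 9 for Mediator, 2 and 9 for cholesterol, 4 and 13 for splicing and 0 and 11 for hnRNP genes. They numbered 4 and 3 for apoptosis, 4 and 8 for ATF4, 2 and 6 for the unfolded protein response, 0 and 2 for heat shock, 3 and 11 for epithelial, 5 and 15 for mesenchymal and 1 and 2 for alveolar genes. Medians turned for senescence markers (-0.12), apoptosis (-0.09), heat shock (-0.0092), immediate early (-0.11), lysosomal (-0.14), neural (-0.15) and endothelial genes (-0.06).

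Among genes with a mean of at least 5 CPM and no overlap between the groups, those that rose most were CALB2, PI3, RP11-669N7.2, SAA1, PSMB8, IL32, PLAC8, IFI6, FAM133A and KCNK6. CALB2, which codes for the calcium-binding protein calretinin (ENSG00000172137.17; chromosome 16, 71358713 to 71390438), rose from 3.30 ± 0.284 to 73.8 ± 9.64 CPM (4.48 ± 0.15, adjusted p = 5.19e-07). PI3, the elastase inhibitor elafin (ENSG00000124102.4; chromosome 20, 45174876 to 45176544), rose from 1.29 ± 0.0970 to 24.4 ± 4.60 CPM (4.24 ± 0.19, adjusted p = 1.83e-06). PSMB8, a catalytic subunit of the immunoproteasome (ENSG00000204264.7; chromosome 6, 32840717 to 32844703), rose from 2.57 ± 0.371 to 25 ± 4.24 CPM (3.28 ± 0.18, adjusted p = 4.8e-06). The acute-phase gene SAA1 rose by 3.46 ± 0.32 (adjusted p = 8.75e-05), the cytokine gene IL32 by 3.13 ± 0.24 (adjusted p = 2.8e-05) and the interferon-induced gene IFI6 by 2.61 ± 0.24 (adjusted p = 8.79e-05). PLAC8 rose by 2.91, FAM133A by 2.45, the potassium channel gene KCNK6 by 2.41 and the antisense transcript RP11-669N7.2 by 3.48. PSMB8 shares exon sequence with PSMB9 and PSMB8-AS1 on the opposite strand, and whether the counting used strand is not given in the sources used here. SAA1 and FAM133A have close paralogues, so their counts are uncertain to that extent.

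By the same rule, the genes that fell most were NTRK3, COL5A1, CACNA1D, WIPF1, IGFN1, F5, IL11, MCTP2, BMP2 and KIRREL3. NTRK3, the receptor kinase for neurotrophin-3 (ENSG00000140538.15; chromosome 15, 87859751 to 88256768), went from 33.3 ± 1.86 to 2.64 ± 0.460 CPM (-3.65 ± 0.16, adjusted p = 1.71e-06). COL5A1, a type V collagen chain (ENSG00000130635.14; chromosome 9, 134641774 to 134844843), went from 89.7 ± 6.14 to 7.64 ± 0.822 CPM (-3.55 ± 0.14, adjusted p = 8.02e-07). The coagulation factor gene F5 went from 37.6 ± 1.14 to 5.16 ± 0.628 CPM (-2.86 ± 0.14, adjusted p = 2.17e-06). IL11, a cytokine of the IL-6 family, went from 38.2 ± 1.49 to 5.71 ± 1.21 CPM (-2.74 ± 0.16, adjusted p = 7.52e-06). The ligand gene BMP2 had a log2 fold change of -2.73 ± 0.23 (adjusted p = 5.11e-05). The calcium channel gene CACNA1D had a log2 fold change of -3.23, WIPF1 -3.00, IGFN1 -2.93, MCTP2 -2.74 and the adhesion gene KIRREL3 -2.70. CACNA1D, WIPF1, IGFN1 and KIRREL3 share exon sequence with genes on the opposite strand.

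**Figure D3:**
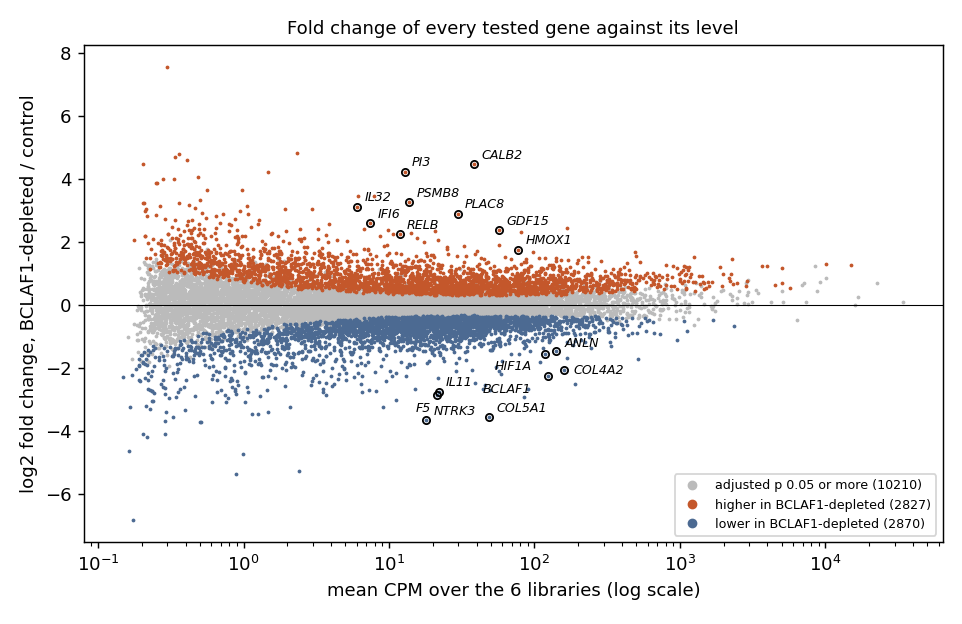
Log2 fold change, BCLAF1-depleted over control (y axis), against mean CPM over the 6 libraries (x axis, log scale) for the 15907 tested genes; each point is 1 gene, orange for 2827 higher, blue for 2870 lower and grey for the others, with some of the named genes circled. Of the circled genes CALB2 at 4.48 and PI3 at 4.24 lie highest, and NTRK3 at -3.65 and COL5A1 at -3.55 lowest.

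Senescence was covered by a list of markers, a list of secretory factors and a list of p53 targets. Of 40 tested secretory phenotype genes, 18 rose and 7 fell (19 and 7 adjusted over the list alone), with a median log2 fold change of 0.36. The stress cytokine gene GDF15 rose from 18.3 to 95.7 CPM (2.39 ± 0.38, adjusted p = 0.0019), the chemokine gene CXCL2 from 5.73 to 25.5 CPM (2.15 ± 0.19), INHBA from 0.153 to 4.52 CPM and CCL5 from 0.145 to 2.82 CPM, whereas IL11 fell. Of 34 tested p53 targets, 13 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.30), among them GADD45A (1.15 ± 0.21), TP53I3 (1.11 ± 0.17), the pro-apoptotic BBC3 (1.04 ± 0.15) and BAX (0.92 ± 0.16). Camera, over 33 lists, gave an adjusted p of 0.00878 for both lists, and for both adjusted p = 0.198 with an estimated correlation. Of 17 tested senescence markers, 3 rose and 2 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.67). That is a smaller share than the 35.8% of all tested genes past the threshold. GDF15, HMGA2 (0.74 ± 0.17) and HMGA1 (0.63 ± 0.14) rose, and RB1, the retinoblastoma gene, had -1.17 ± 0.26. The proliferation marker MKI67, with -0.49 ± 0.17, was named after its value was seen, as were CDKN1A and LMNB1. CDKN1A, which codes for the cell cycle inhibitor p21, was at 0.15 ± 0.12 (adjusted p = 0.361) and LMNB1, the lamin gene whose loss is used as a senescence marker, at -0.31 ± 0.13 (adjusted p = 0.0871), which passed without BCLAF1-depleted replicate 1 (adjusted p = 0.0188), with the GC and length trend removed (0.0406) and with library totals alone (0.0249). Without BCLAF1-depleted replicate 1 the p53 list had 4 lower genes, a median of 0.16 and a camera adjusted p of 0.0693. The secretory list had 4 lower genes without control replicate 1 or 2, a median of 0.60 without control replicate 3 and of 0.57 with no low-count filter, and an adjusted p of 0.0739 with the GC and length trend removed and BCLAF1-depleted replicate 1 left out. Higher and lower senescence markers numbered 2 and 1 without control replicate 1 or 2, 3 and 1 without control replicate 3 or BCLAF1-depleted replicate 2, and 4 and 5 without BCLAF1-depleted replicate 1. MKI67 lost its call without each control library and without BCLAF1-depleted replicate 2 (adjusted p up to 0.178), with the GC and length trend removed (-0.31, 0.155), with upper-quartile scaling (0.0597) and with only genes of at least 5 CPM (0.0546), and HMGA1 without control replicates 1 (0.0535) and 2 (0.0525).

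Genes of cell division were lower. Of 44 tested G2/M genes, 28 fell and 0 rose (30 and 0 adjusted over the list alone), with a median log2 fold change of -0.60 and a camera adjusted p of 8.93e-07 (adjusted p = 0.289 with an estimated correlation). ANLN, a scaffold of the cytokinetic ring, went from 206 to 75.6 CPM (-1.45 ± 0.25, adjusted p = 0.00243), the spindle checkpoint kinase gene BUB1 from 50.4 to 18.6 CPM (-1.44 ± 0.19, adjusted p = 0.000596), DLGAP5 (-1.23 ± 0.16) and ECT2 from 175 to 77.3 CPM (-1.18 ± 0.23). Of 45 tested G1/S genes, 14 fell and 2 rose (15 and 4 adjusted over the list alone; median -0.17), with a camera adjusted p of 0.0288 (adjusted p = 0.398 with an estimated correlation). E2F8 (-1.13 ± 0.21), the replicative polymerase gene POLA1 (-0.96 ± 0.13) and RFC3 (-0.83 ± 0.18) fell. CCND1, which codes for cyclin D1, rose from 198 to 417 CPM (1.07 ± 0.13, adjusted p = 0.000402), as did CLSPN (0.69 ± 0.20), named after its value was seen. Of 45 tested DNA repair genes, 14 fell and 1 rose (16 and 2 adjusted over the list alone; median -0.26), with a camera adjusted p of 0.0118 (adjusted p = 0.462 with an estimated correlation). XRCC2 (-0.73 ± 0.17) and TOPBP1 (-0.77 ± 0.19) fell, and the 1 gene that rose was FANCF (0.42 ± 0.12), named after its value was seen. With the GC and length trend removed the DNA repair list had 7 lower and 4 higher genes, a median of -0.14 and a camera adjusted p of 0.242. Without control replicates 1, 2 and 3 the lower genes numbered 7, 6 and 8 of the G1/S list and 5, 5 and 8 of the DNA repair list, and 9 of the G1/S list without BCLAF1-depleted replicate 2. The higher G1/S genes numbered 1 without any 1 control or BCLAF1-depleted replicate 2. Without BCLAF1-depleted replicate 1 the higher genes numbered 4 of the G1/S, 3 of the DNA repair and 2 of the G2/M list, and the lower DNA repair genes 22. CLSPN and FANCF lost their calls without each control (adjusted p up to 0.0848 and 0.11) and CLSPN without BCLAF1-depleted replicate 2 (0.0512), and the G1/S list did with only genes of at least 5 CPM (0.0607).

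Autophagy genes changed in both directions, but no more often than tested genes in all, of which 35.8% passed the threshold. Of 44 tested core autophagy genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone; median -0.10, camera adjusted p = 0.3). The genes that rose were VAMP8, a SNARE of the autophagosome and lysosome (11.4 to 28.8 CPM, 1.34 ± 0.16, adjusted p = 0.000332), the cargo receptor gene SQSTM1, which codes for p62 (489 to 770 CPM, 0.66 ± 0.14, adjusted p = 0.00581), ATG12 (0.60 ± 0.11) and GABARAP (0.58 ± 0.19). Among those that fell were PIK3R4, a subunit of the class III phosphoinositide 3-kinase (-0.89 ± 0.19), and ATG2B (-0.72 ± 0.15). MAP1LC3B, which codes for LC3B, was at -0.10 ± 0.13 (adjusted p = 0.564). Of 42 tested lysosomal genes, 6 rose and 4 fell (5 and 4 adjusted over the list alone, median 0.08, camera adjusted p = 0.623), a smaller share than among all tested genes. The median of the lysosomal list turned to -0.14 with library totals as the only scaling. The protease gene CTSH rose by 0.81 ± 0.18, and those that fell included MITF (-0.78 ± 0.19), LAMP2 (-0.58 ± 0.18) and SCARB2 (-0.45 ± 0.13). Of 33 tested mTOR and AMPK pathway genes, 2 rose and 10 fell (2 and 11 adjusted over the list alone; median -0.12, camera adjusted p = 0.0801). MTOR went from 52.2 to 25.1 CPM (-1.06 ± 0.12, adjusted p = 0.000239), and the translation repressor gene EIF4EBP2 (-0.91 ± 0.13) and the AMPK subunit gene PRKAA2 (-0.72 ± 0.14) also fell, while SESN2 (0.90 ± 0.17, and 0.33 with log2(FPKM + 1)) and AKT1S1 (0.64 ± 0.13) rose. SQSTM1, ATG12, GABARAP, MAP1LC3B, SCARB2 and AKT1S1 were named after their values were seen. Higher and lower autophagy genes numbered 3 and 4 without control replicate 1, 2 and 4 without control replicate 2, and 7 and 14 without BCLAF1-depleted replicate 1. For lysosomal genes these were 1 and 2 without control replicate 1 or 2, 2 and 1 without control replicate 3, and 8 and 7 or 7 and 2 without BCLAF1-depleted replicate 1 or 3. By fry, which asks only whether a list's own genes move one way, the autophagy (adjusted p = 0.017) and mTOR lists (0.0366) passed as lower. Neither passed fry with the GC and length trend removed (0.933 and 0.179), nor did the mTOR list with the replicate block (0.072). By camera, the mTOR list passed without BCLAF1-depleted replicate 1 (adjusted p = 0.0437, 4 higher genes) and with no low-count filter (0.0119), and without control replicates 1, 2 and 3 its lower genes numbered 5, 6 and 6. LAMP2, SCARB2 and GABARAP lost their calls without any 1 of the controls or of BCLAF1-depleted replicates 2 and 3 (adjusted p up to 0.111, 0.097 and 0.128) and with the GC and length trend removed (-0.39, -0.17 and 0.36; adjusted p = 0.0626, 0.292 and 0.142), MITF without control replicate 3 (0.0565) and SQSTM1 without control replicate 2 (0.0502).

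Mediator subunit genes moved both ways as well, with 10 of 32 past the threshold, a smaller share than the 35.8% of all tested genes. Of 32 tested, 4 rose and 6 fell (4 and 6 adjusted over the list alone; median -0.18, camera adjusted p = 0.309). MED17, a core subunit of the head module, went from 8.85 ± 0.0954 to 3.97 ± 1.28 CPM (-1.15 ± 0.21, adjusted p = 0.00321), and MED13L, of the kinase module, from 73.2 to 44.5 CPM (-0.72 ± 0.15, adjusted p = 0.00569). The subunit genes that rose were MED19 (35 to 76.5 CPM, 1.13 ± 0.25, adjusted p = 0.00729), MED31 (0.83 ± 0.20), MED18 (0.71 ± 0.17) and MED11 (0.40 ± 0.13), of which MED18 and MED11 were named after their values were seen. The list passed fry as lower (adjusted p = 0.0145), but not with the replicate block (0.0787). Higher and lower subunit genes numbered 3 and 2 without control replicate 1 or BCLAF1-depleted replicate 2, 1 and 2 without control replicate 2, 3 and 3 without control replicate 3, and 6 and 9 without BCLAF1-depleted replicate 1. MED31 and MED18 lost their calls without control replicate 2 (adjusted p = 0.0537 and 0.05), and MED11 without any 1 control (up to 0.142) or BCLAF1-depleted replicate 2 (0.069), with the GC and length trend removed (0.067, adjusted p = 0.684), with library totals alone (0.17, adjusted p = 0.483) and with no low-count filter (0.0929). MED17 and MED31 share exon sequence with TAF1D and TXNDC17 on the opposite strand.

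Genes of the interferon and NF-kB responses rose together. Of 38 tested interferon response genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone; median 0.59), with a camera adjusted p of 1.96e-06 (adjusted p = 0.193 with an estimated correlation). PSMB8 and IFI6 rose as above, IFI44L rose from 0.198 to 1.09 CPM (2.45 ± 0.42, adjusted p = 0.00255), and IFI27 had 0.0526 CPM in controls, under the floor, and 0.92 CPM after depletion. The transcription factor gene STAT2 (-0.88 ± 0.20, adjusted p = 0.00787), named after its value was seen, was among those that fell. Of 28 tested NF-kB response genes, 18 rose and 0 fell (19 and 0 adjusted over the list alone; median 0.82), with a camera adjusted p of 9.95e-08 (adjusted p = 0.0924 with an estimated correlation). RELB, an NF-kB subunit, rose from 4.10 to 19.6 CPM (2.25 ± 0.14, adjusted p = 1.05e-05), CXCL2 and IL32 as above, and BIRC3, an inhibitor of apoptosis, from 22.4 to 63.5 CPM (1.50 ± 0.12, adjusted p = 4.44e-05). The NF-kB list shared 5 tested genes with the secretory phenotype list (CCL20, CXCL1, CXCL2, CXCL8 and ICAM1). Both lists kept their calls without any 1 of the 6 libraries, while the lower interferon genes numbered 4 without BCLAF1-depleted replicate 1 and 1 without any 1 other library.

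Among metabolic lists, NRF2 targets rose, and hypoxia and fatty acid genes fell. Of 36 tested NRF2 targets, 11 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.22), with a camera adjusted p of 0.0118 (adjusted p = 0.343 with an estimated correlation). HMOX1, heme oxygenase 1, rose from 35 to 119 CPM (1.77 ± 0.12, adjusted p = 1.43e-05), CBR3 by 1.26 ± 0.16, the glutathione peroxidase gene GPX2 by 1.23 ± 0.17 and OSGIN1 by 1.13 ± 0.14; IDH1 (-0.90 ± 0.18), named after its value was seen, fell. Of 40 tested hypoxia and glycolysis genes, 3 rose and 19 fell (3 and 21 adjusted over the list alone; median -0.46), with a camera adjusted p of 0.00507 (adjusted p = 0.462 with an estimated correlation). HIF1A, the oxygen-regulated transcription factor gene, went from 177 to 60.4 CPM (-1.55 ± 0.23, adjusted p = 0.00131), ALDOC from 4.60 to 1.95 CPM (-1.24 ± 0.26) and CA9 from 4.69 to 0.120 CPM, close to the floor. ANGPTL4 (1.42 ± 0.17), ADM (1.17 ± 0.14) and EGLN3 (1.05 ± 0.13) rose, the last pair named after their values were seen. Of 31 tested fatty acid genes, 4 rose and 15 fell (5 and 15 adjusted over the list alone; median -0.40), with a camera adjusted p of 0.0372 (adjusted p = 0.398 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, went from 477 to 196 CPM (-1.29 ± 0.18), the desaturase gene SCD from 458 to 203 CPM (-1.17 ± 0.16), ACSL4 from 25.7 to 10.8 CPM and PPARA from 5.20 to 2.01 CPM. ELOVL1 (0.84 ± 0.12), DGAT2 (1.08 ± 0.34), PPARG (0.58 ± 0.20) and CPT2 (0.40 ± 0.12) rose, all named after their values were seen. Of 26 tested cholesterol synthesis genes, 13 passed in both directions (median -0.05, camera adjusted p = 0.381; 13 adjusted over the list alone), with HMGCS1 (1.19 ± 0.18) and TM7SF2 (1.19 ± 0.21) higher and SREBF1 (-0.74 ± 0.12) lower. With the GC and length trend removed the fatty acid list had a median of -0.27 and a camera adjusted p of 0.181, and without BCLAF1-depleted replicate 1 the NRF2 list had 6 lower genes and an adjusted p of 0.0997. Without control replicates 1, 2 and 3 the lower genes numbered 10, 9 and 10 of the hypoxia list and 8, 7 and 8 of the fatty acid list, and the higher NRF2 targets 7, 7 and 8. The higher fatty acid genes numbered 1 without any 1 control and 2 without BCLAF1-depleted replicate 2. Cholesterol genes past the threshold numbered 7, 8 and 7 without control replicates 1, 2 and 3. DGAT2, PPARG and CPT2 lost their calls without any 1 control (adjusted p up to 0.119, 0.148 and 0.134), DGAT2 also without BCLAF1-depleted replicate 2 or 3, PPARG without 1 or 3 and CPT2 without 2.

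Ribosomal protein genes rose as a class. Of 57 tested, 49 rose and 0 fell (54 and 0 adjusted over the list alone; median 0.71), with a camera adjusted p of 1.78e-13 (adjusted p = 0.462 with an estimated correlation). RPLP1 went from 1221 to 3369 CPM (1.46 ± 0.30, adjusted p = 0.00546), RPL38 from 526 to 1263 CPM (1.26 ± 0.21) and RPS12 from 630 to 1506 CPM (1.26 ± 0.20); these genes have many processed pseudogenes, with which reads may be shared. Of 45 tested nuclear genes of oxidative phosphorylation, 25 rose and 3 fell (28 and 3 adjusted over the list alone; median 0.47), with a camera adjusted p of 0.000686 (adjusted p = 0.475 with an estimated correlation). COX6C (1.05 ± 0.23), NDUFA1 (0.87 ± 0.17) and NDUFB9 (0.86 ± 0.19) rose, and NDUFS1 (-0.64 ± 0.13), SDHA (-0.49 ± 0.13) and UQCRC1 (-0.36 ± 0.12), named after their values were seen, fell. With the GC and length trend removed 41 ribosomal protein genes were higher (median 0.67, camera adjusted p = 1.55e-11), and 17 oxidative phosphorylation genes (median 0.27, camera adjusted p = 0.0151). Without control replicates 1, 2 and 3 the higher genes numbered 20, 19 and 21 of the ribosomal list and 8, 8 and 15 of the oxidative phosphorylation list, and 15 of the latter without BCLAF1-depleted replicate 2. Its lower genes numbered 1 without any 1 control and 5 without BCLAF1-depleted replicate 1. SDHA and UQCRC1 lost their calls without any 1 control (adjusted p up to 0.0805 and 0.153), and UQCRC1 without BCLAF1-depleted replicate 2 (0.0634).

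Mitochondrially encoded and histone genes were nearer to the threshold. Of 13 tested mitochondrially encoded genes, 3 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.72), with a camera adjusted p of 0.0479 (adjusted p = 0.672 with an estimated correlation). They were MT-ND6 (1.17 ± 0.26), MT-ND1 (1.32 ± 0.43) and MT-ND3 (1.27 ± 0.36). BCLAF1-depleted replicate 3 carried most of it: without that library the median was 0.22 and the adjusted p 0.173. The call also ended without control replicates 1, 2 and 3 (0.0731, 0.0503 and 0.0555), with the GC and length trend removed (median 0.46, adjusted p = 0.329) and with upper-quartile scaling (0.0596), and the list did not pass fry (0.29). MT-ND1 lost its call with that trend removed (0.0884), with the DESeq2 Wald test (0.0943) and limma-voom (0.0609) and without any 1 control (up to 0.112), and MT-ND3 with the DESeq2 Wald test (0.0556) and without any 1 control (up to 0.0728). The higher genes numbered 1 without any 1 control, 8 without BCLAF1-depleted replicate 1 and 6 without replicate 2. Of 17 tested histone genes, whose replication-dependent transcripts mostly lack a poly(A) tail, 6 rose and 0 fell (6 and 0 adjusted over the list alone; median 0.36), with a camera adjusted p of 0.0395 (adjusted p = 0.462 with an estimated correlation). HIST1H1C rose from 14.7 to 44.0 CPM (1.58 ± 0.23, adjusted p = 0.00119). The histone call ended with the GC and length trend removed (median 0.18, 3 higher genes, adjusted p = 0.444), without control replicate 1 (median 0.16, adjusted p = 0.0781) and without BCLAF1-depleted replicates 1 (0.179) and 2 (0.0719), and 3 and 2 histone genes were higher without control replicates 1 and 2.

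**Figure D4:**
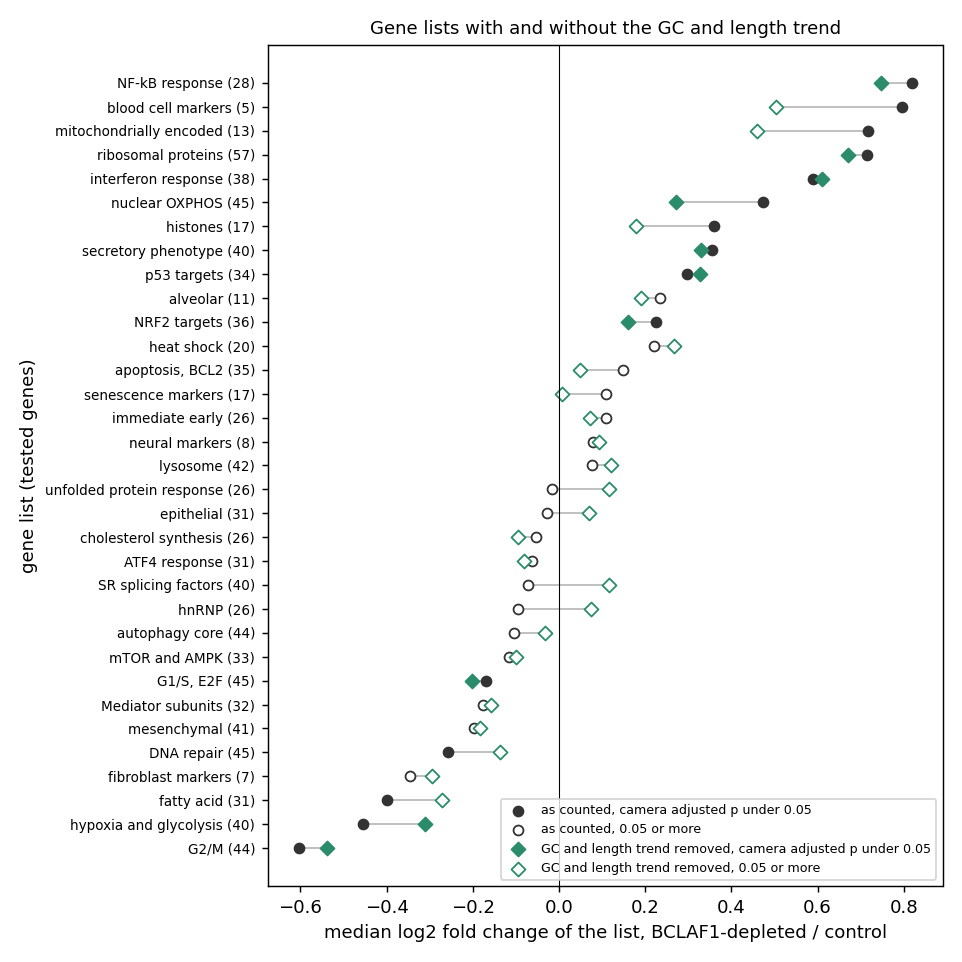
Median log2 fold change of each of the 33 lists (x axis; list names with their numbers of tested genes on the y axis) as counted (circles) and with the GC and length trend removed (diamonds); filled symbols have a camera adjusted p under 0.05. G2/M genes lie lowest at -0.60 and NF-kB response genes highest at 0.82, and both stay filled with the trend removed.

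Splicing and hnRNP genes did not pass camera, nor fry (adjusted p = 0.355 and 0.195). Of 40 tested SR and splicing genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone); the median was -0.07, the mean 0.02 and the camera adjusted p 0.643, with direction down. The helicase gene DDX17 went from 206 to 111 CPM (-0.88 ± 0.16, adjusted p = 0.00289) and U2AF1L4 rose by 1.41 ± 0.31. RBM25 (1.03 ± 0.29) and SRSF11 (0.97 ± 0.28) rose, with 0.58 each without BCLAF1-depleted replicate 3, and lost their calls without any 1 control (adjusted p up to 0.094 and 0.0823) or BCLAF1-depleted replicate 2 (0.0532 and 0.0612), SRSF11 also without replicate 3 (0.0531). Of 26 tested hnRNP genes, HNRNPUL1 (-0.55 ± 0.14), HNRNPH2 (-0.55 ± 0.18) and PTBP1 (-0.48 ± 0.15) fell and PCBP2 (0.42 ± 0.14) rose, while 0 passed adjusted over the list alone (median -0.09, camera adjusted p = 0.391). Higher and lower splicing genes numbered 2 and 3 without control replicate 1 or 2, 1 and 3 without control replicate 3, and 10 and 12 or 4 and 4 without BCLAF1-depleted replicate 1 or 2. For hnRNP genes these were 0 and 0 without any 1 control, and 5 and 11, 0 and 1 and 0 and 4 without BCLAF1-depleted replicates 1, 2 and 3. The 4 hnRNP calls were lost without any 1 control (adjusted p up to 0.184), and all but that of HNRNPUL1 without BCLAF1-depleted replicate 2 or 3 (up to 0.114). With the GC and length trend removed the medians were 0.12 for splicing and 0.07 for hnRNP genes (camera adjusted p = 0.444 and 0.8), and PTBP1 lost its call (adjusted p = 0.0825).

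Stress response lists did not pass camera, although single members changed. By fry, the apoptosis (adjusted p = 0.00224), heat shock (0.0465) and immediate early lists (0.0366) passed as higher. The heat shock and immediate early lists no longer passed fry with the GC and length trend removed (0.0897 and 0.431) or with the replicate block (0.128 each). The apoptosis list passed it in both settings (0.00369 and 0.0261). Of 35 tested apoptosis genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone; median 0.15, camera adjusted p = 0.221), with BIRC3, BBC3 and the death receptor gene TNFRSF10A (0.94 ± 0.13) higher and CASP9 (-1.08 ± 0.15), BCL2L11 (-0.90 ± 0.22) and MCL1 (-0.48 ± 0.11) lower. Of 31 tested ATF4 targets, 9 passed in both directions (9 adjusted over the list alone); the median was -0.06, the mean 0.03 and the camera adjusted p 0.524, with direction down. NUPR1 rose from 3.68 to 17.6 CPM (2.26 ± 0.20), and DDIT3, which codes for CHOP, by 1.14 ± 0.25, while VLDLR went from 46.6 to 10.9 CPM (-2.10 ± 0.14) and the serine synthesis gene PHGDH from 45.7 to 22.5 CPM (-1.02 ± 0.12). Of 26 tested genes of the unfolded protein response, 10 passed in both directions (11 adjusted over the list alone); the median was -0.02, the mean 0.02 and the camera adjusted p 0.793, with direction up. SDF2L1 (0.80 ± 0.15) and DNAJB11 (0.63 ± 0.14, and 0.33 with log2(FPKM + 1)) rose and SEC24D (-1.01 ± 0.25) fell. Of 20 tested heat shock genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.22, camera adjusted p = 0.102), with HSPA8 at 0.68 ± 0.19 and DNAJB1 at -0.37 ± 0.12; HSPA1B (0.57 ± 0.13) and HSPA1A (0.49 ± 0.13) are near-identical copies and are uncertain. Of 26 tested immediate early genes, 12 passed in both directions (12 adjusted over the list alone; median 0.11, camera adjusted p = 0.357), with EGR1 (1.63 ± 0.17) and FOSL1 (1.25 ± 0.21) higher and FOS (-1.33 ± 0.20) and DUSP1 (-1.30 ± 0.13) lower. BCL2L11, MCL1, PHGDH and DNAJB1 were named after their values were seen. Without control replicate 1 or 2, 0 heat shock genes passed, and higher and lower genes numbered 3 and 0 without control replicate 3 and 9 and 2 without BCLAF1-depleted replicate 1. For ATF4 targets these were 4 and 3 without any 1 control, and 5 and 12 without BCLAF1-depleted replicate 1, when apoptosis genes had 11 and 6. Genes of the unfolded protein response had 3 and 1 without control replicate 1 or 3, 4 and 1 without control replicate 2 or BCLAF1-depleted replicate 2, and 7 and 8 or 6 and 3 without BCLAF1-depleted replicate 1 or 3. The heat shock list passed without BCLAF1-depleted replicate 2 (0.0429, 5 higher and 0 lower), while HSPA8 lost its call without any 1 control (up to 0.104) and HSPA1A and HSPA1B without control replicate 1 or 2 (up to 0.0882 and 0.0574), and HSPA1A with the GC and length trend removed (0.0807). MCL1 lost its call without control replicates 1 (0.0681) and 2 (0.0656), DNAJB1 without any 1 control (up to 0.138) or BCLAF1-depleted replicate 2 or 3, and SEC24D without BCLAF1-depleted replicate 2 (0.0562).

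The epithelial, mesenchymal and alveolar lists did not pass camera. By fry, the epithelial (adjusted p = 0.0448), mesenchymal (0.0145) and fibroblast lists (0.0448) passed as lower and the alveolar list (0.0145) as higher. With the GC and length trend removed the fibroblast (0.0634) and alveolar lists (0.133) no longer passed fry. With the replicate block the mesenchymal (0.0698) and fibroblast lists (0.105) did not. Of 31 tested epithelial genes, 6 rose and 8 fell (6 and 8 adjusted over the list alone; median -0.03, camera adjusted p = 0.684), with the tight junction genes CLDN1 (1.14 ± 0.13) and CLDN2 (-1.26 ± 0.13) going opposite ways. Of 41 tested mesenchymal genes, 9 rose and 11 fell (10 and 13 adjusted over the list alone; median -0.20, camera adjusted p = 0.288). The basement membrane collagen genes COL4A1 (85.6 to 13.2 CPM, -2.69 ± 0.16) and COL4A2 (258 to 61.8 CPM, -2.06 ± 0.13) fell, and ANKRD1 rose from 4.82 to 23.4 CPM (2.28 ± 0.15). Of 11 tested alveolar markers, CAV1 (1.01 ± 0.13) and SFTPD rose and LPCAT1 (-0.93 ± 0.17) and FOXA2 fell (2 and 2 adjusted over the list alone; median 0.23, camera adjusted p = 0.363). Of markers of other cell types, the fibroblast genes FBLN1 (-1.44 ± 0.12) and COL1A1 (-0.84 ± 0.13) fell among 7 tested (2 adjusted over the list alone; camera adjusted p = 0.292), both of which A549 cells express in the controls at 72.7 and 17.7 CPM. NEFM rose from 0.214 to 0.628 CPM among 8 tested neural genes (0 adjusted over the list alone; camera adjusted p = 0.63), and of 2 tested endothelial genes CDH5 rose to 1.64 CPM and PECAM1 fell to 0.581 CPM. Of 5 tested blood cell markers, ITGAM rose from 0.656 to 1.30 CPM (1 adjusted over the list alone; median 0.79, camera adjusted p = 0.0479, and adjusted p = 0.462 with an estimated correlation). Higher and lower epithelial genes numbered 3 and 4 without control replicate 1, 3 and 3 without control replicate 2 or 3, and 4 and 4 without BCLAF1-depleted replicate 2, and their median was 0.04 without BCLAF1-depleted replicate 3. Without BCLAF1-depleted replicate 1, 17 mesenchymal genes were lower and 2 neural genes higher. Alveolar markers had 1 higher and 1 lower without any 1 control, and 1 and 2 without BCLAF1-depleted replicate 2 or 3. The blood list call ended with the GC and length trend removed (median 0.50, adjusted p = 0.159), with upper-quartile scaling (0.0596), with no low-count filter (0.0785) and without control replicate 1 (0.0772) or BCLAF1-depleted replicate 1 (0.0881) or 3 (0.133), and SFTPD, FOXA2, NEFM and PECAM1 lost their calls without any 1 control (adjusted p up to 0.194, 0.062, 0.0994 and 0.164). SFTPD and PECAM1 lost theirs also without any 1 BCLAF1-depleted library and with that trend removed (0.179 and 0.0672), NEFM without replicate 3 (0.0927), and ITGAM without control replicate 1 (0.0542) or 2 (0.0949) or BCLAF1-depleted replicate 2 (0.0526).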

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

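Of the tests in this part, those on mitochondrially encoded transcripts and the GC and length test on interferon and NF-kB genes were chosen only after the result was seen. The deposited FPKM values, used elsewhere here only in alternatives, imply a library total that differed from the summed counts by group. Set to 100 in control replicate 1, the ratio of summed counts to that total was 99.5 ± 0.400 in controls and 95.5 ± 2.17 in BCLAF1-depleted libraries, a difference of -4.094. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Summed counts exceeded the implied total in all 6 libraries, by a factor of 1.19 to 1.27 with the exon lengths used here, so the ratio is not a share of reads and does not show reads outside the listed genes. What it reflects stays open.

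Fold changes followed gene length, from a median of 0.346 in the shortest quintile of genes to -0.188 in the longest. GC content gave a partial Spearman correlation of 0.076 across 15739 genes, given exon length and genomic span, which leaves its part open; genes are not independent replicates. Exon length, given span and GC content, gave -0.115, and span, given exon length and GC content, gave -0.16, so a length bias of the libraries, such as differing RNA integrity, and a loss of transcripts from long genes both stay open and may act together. An effect of BCLAF1 on long transcripts has the same form in these data and was not tested apart from them.

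Mitochondrially encoded transcripts were higher mainly in BCLAF1-depleted replicate 3. Without that library the list's median was 0.219, so a single library could account for most of the rise. In it the ribosomal RNA MT-RNR2 lay 0.626 above the control mean on the log2 scale and MT-RNR1 0.514, each below 12 of the 13 protein-coding transcripts (0.481 to 2.252, median 1.422). Whether RNA of all kinds from the mitochondrial genome rose alike there stays open, as does whether the culture or the library differed. In replicates 1 and 2 the medians of the 13 were 0.245 and 0.301, MT-RNR2 lay at -0.131 and -0.33 and MT-RNR1 at 0.244 and 0.56.

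Interferon and NF-kB genes were higher after BCLAF1 depletion. Trends with GC content and exon length argue little for the rise, since the smaller share of the median kept by either list was 91.4% once they were removed. Genomic span was not part of that correction, so this test cannot decide on a trend with span. Blood cells in the cultures would bring abundant blood transcripts, and 7 such genes, of which 5 are in the table, summed to at most 0.908 CPM in a BCLAF1-depleted library and 0.657 to 0.805 CPM in controls. The blood marker list written beforehand did pass camera as higher (5 tested genes, median 0.79, adjusted p = 0.0479). Its 1 called gene, ITGAM, reached 1.30 CPM after depletion. A single library does not carry it, as the largest camera adjusted p of either list with 1 library left out was 0.000338. That holds for the preset correlation, as neither list passed camera with an estimated one (interferon 0.193, NF-kB 0.0924). The estimated correlation was 0.0241 for interferon and -0.0258 for NF-kB genes, against the preset 0.01. For NF-kB genes a correlation above the preset one thus does not account for the lost call. A response of the cells to lower BCLAF1 remains a hypothesis, as does one to the hairpin or virus itself, since 1 hairpin against BCLAF1 may differ from the luciferase hairpin in other ways and no second hairpin was analysed here.

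The 6 libraries split in 10 ways into groups of 3, too few for a share under 0.05. Only 1 of the 10 splits, the real one, gave 2827 higher genes, and the highest of the others with edgeR was 0. For lower genes the real split gave 2870, the highest other 0, and 1 of 10 splits reached the real count. For gene lists the real split gave 15 and the highest other 12, and again 1 of 10 reached the real count. The list tests called many lists in splits that mix the groups, among them the mitochondrially encoded list in 9 of 9 other splits, G2/M in 8 and NF-kB in 7. Each of these splits holds unequal numbers of the groups on each side, so part of the real difference stays in it. The list calls there need not be false. The real difference also widens the spread within each side, so the count of 0 genes there was largely fixed in advance.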

How the results depend on the processing

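BCLAF1 kept its direction and call in all 23 alternatives with a fit over all genes (log2 fold change -2.55 to -1.88, largest adjusted p 0.00173), and no gene called both in an alternative and with the settings of the report changed sign. Of 205 genes recomputed, 101 kept their direction and side of the threshold in every setting; of 4689 values, 623 were no longer past it and 11 turned sign. The number of higher genes moved by over 1.5 times with library totals alone (1283, with 3662 lower, 25.95% of calls higher), and the median of all genes moved to -0.21. That setting leaves out the TMM factors, which were 1.08, 1.08 and 1.10 in controls and 1.05, 0.94 and 0.80 in BCLAF1-depleted replicates 1 to 3. The near-even split of the report therefore depends on such scaling. The number of higher genes also moved by over 1.5 times with log2(FPKM + 1) (1131, with 4453 lower, 20.25%), log2(FPKM + 0.1) (1126, with 4381 lower, 20.45%) and log2(FPKM + 1) without a filter (573, with 2057 lower, 21.79%). The FPKM settings also applied no TMM factors, and with log2(FPKM + 0.1) the median of all genes was -0.25. They are therefore not separate evidence on the scaling. Whether scaling accounts for all of their shift was not tested. Stricter thresholds by construction gave 962 higher and 817 lower genes at 2-fold or more, 479 and 528 by glmTreat against 1.5-fold, and 1149 and 1287 at an adjusted p under 0.01. With 1 library left out, fewer samples by construction, higher genes ranged from 1383 to 3741 and lower genes from 1549 to 4195, highest without BCLAF1-depleted replicate 1. The GC and length correction without BCLAF1-depleted replicate 2, added after seeing the data, gave 1777 lower genes, and without replicate 1 it gave 8 lists past the threshold in place of 15. With an estimated correlation 0 lists passed camera (lowest adjusted p 0.0924, NF-kB), although 5 lists had an unadjusted p under 0.05. Estimated correlations were -0.0258 for NF-kB genes, -0.0164 for secretory genes and -0.0091 for p53 targets, all below the preset 0.01. A correlation above the preset one thus does not account for the lost calls of these lists. Fry passed 24, and fewer with the replicate block or with the GC and length trend removed. With the block it lost, among others, ribosomal protein (0.072), DNA repair (0.072) and oxidative phosphorylation genes (0.102). With the trend removed it lost, among others, DNA repair (0.0793) and oxidative phosphorylation genes (0.0901). Whether the replicate numbers pair the libraries is not given in the labels. Deviations of same-numbered libraries correlated weakly, at 0.036, 0.047 and 0.119, and those of other pairs at -0.076 to 0.033. Each library thus correlated best with its own number, a hint from the data only, and pairing stays open. The replicate block gave 2886 higher and 3121 lower genes; with it MED23 passed (-0.60, adjusted p = 0.0456), and SFTPD (0.0676), PECAM1 (0.0524), UQCRC1 (0.0708), MKI67 (0.0608), DNAJB1 (0.0526), FARSA (0.062) and EPRS (0.0867), among others, no longer did. Results that turned sign, none past the threshold in either setting, the cause was not tested: THRAP3, at -0.12 with library totals, -0.18 with log2(FPKM + 1) with and without a filter and -0.19 with log2(FPKM + 0.1); CDKN1A, at -0.059, -0.14, -0.14 and -0.15 in the same settings, -0.0078 with the GC and length correction and block and -0.16 with the correction without BCLAF1-depleted replicate 1; MAP1LC3B, at 0.029 in that last setting. Lists whose camera direction turned are given with their median: with library totals lysosome (-0.14) and unfolded protein response (-0.25); for the latter also with no filter (-0.10), without control replicate 3 (-0.069) and without BCLAF1-depleted replicate 1 (-0.037), in a range of -0.069 to 0.046 with 1 library left out; with no filter neural markers (0.037). With the GC and length correction, splicing was at 0.12, hnRNP at 0.073; with the block as well 0.11 and 0.058; without BCLAF1-depleted replicate 1 0.16 and 0.11, senescence markers -0.077 and immediate early 0.0018; without replicate 2 0.11 and 0.13; without replicate 3 splicing was at 0.040 and mitochondrially encoded genes at -0.024. Medians that turned while the camera direction did not were, with library totals, senescence markers (-0.12), apoptosis (-0.092), heat shock (-0.0092), immediate early (-0.11) and neural (-0.15). The epithelial median did with upper-quartile scaling (0.014), at least 5 CPM (0.0024), without BCLAF1-depleted replicate 3 (0.041), and with the GC and length correction alone (0.069), with the block (0.017) or without replicate 3 (0.065), and that of the unfolded protein response with upper-quartile scaling (0.028), at least 5 CPM (0.016), without control replicate 1 (0.014), without BCLAF1-depleted replicates 2 (0.046) and 3 (0.0058), and with the correction alone (0.12), with the block (0.10) or without replicate 1 (0.075), 2 (0.089) or 3 (0.13). The alveolar median turned with at least 5 CPM (-0.016), and with the correction those of autophagy without replicate 2 (0.010), senescence markers with the block (-0.0078) and apoptosis without replicate 1 (-0.032). The 2 endothelial genes, not tested as a list, had -0.063 with library totals. Depth limits genes below the filter, which were not tested, and changes under 2-fold.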

Other observations

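The 6 lists in this part were chosen after the data had been seen, and the tests on antigen presentation genes and collagen genes were chosen only after their result was seen; all genes named here were chosen after their values were seen. HLA class I and peptide loading genes rose together. Of 19 tested, 16 rose and 0 fell, with a median log2 fold change of 0.933 and a camera adjusted p over the 6 lists of 1.42e-06 (adjusted p = 0.125 with an estimated correlation). The immunoproteasome genes PSMB8 (3.28 ± 0.18), PSMB9 (2.05 ± 0.18) and PSMB10 (1.32 ± 0.20), the peptide transporter gene TAP2 (1.13 ± 0.13), the loading factor gene TAPBP (1.08 ± 0.14) and the class I gene HLA-B (0.93 ± 0.12) were higher, with no overlap between the libraries of the groups. HLA-C (0.53 ± 0.15) rose less, can share reads with other class I genes, and lost its call without any 1 control library (adjusted p up to 0.0912), with library totals alone (0.171) and with the GC and length trend removed (0.0941). With the GC and length trend removed 12 rose and 0 fell (adjusted p = 4.94e-06). Of the 19 genes 4 also stand in the interferon list. Genes of the constitutive proteasome, which degrades proteins tagged with ubiquitin, rose as well: 18 of 33 tested identifiers rose and 0 fell (median 0.457, adjusted p = 5.89e-06, and adjusted p = 0.125 with an estimated correlation), among them PSMA4 (0.99 ± 0.22), PSMD4 (0.96 ± 0.19) and PSMD1 (0.94 ± 0.20). With the trend removed 17 rose and 0 fell (adjusted p = 4.94e-06). A coordinated rise of peptide production and presentation may be part of the response to BCLAF1 depletion, as a hypothesis found and tested on the same data.

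Collagen genes fell more often than they rose. Of 26 tested, 11 fell and 4 rose (median -0.412, camera adjusted p = 0.0189, and adjusted p = 0.297 with an estimated correlation), and with the GC and length trend removed the list no longer passed (0.0887), with a median of -0.29 and 10 lower and 5 higher genes. Beside COL5A1, COL4A1 and COL4A2, COL18A1 was lower (-1.09 ± 0.11), while COL11A1 (2.57 ± 0.28), COL13A1 (2.24 ± 0.44), COL16A1 (1.22 ± 0.27) and COL17A1 (0.83 ± 0.14) were higher. Long non-coding genes rose by a median of 0.244, with 357 higher and 113 lower of 1811 tested (adjusted p = 0.0019, and adjusted p = 0.315 with an estimated correlation), and did not pass with the trend removed (0.76). The lists of 377 zinc finger genes (44 higher, 62 lower, adjusted p = 0.266) and of 20 cytosolic tRNA synthetase genes (adjusted p = 0.308) did not pass camera; by fry, which compares a list with no other genes, the adjusted p was 0.1 and 0.00417. Of the synthetases FARSA rose (0.33 ± 0.11) and EPRS, IARS, LARS and YARS fell, IARS most with -0.85 ± 0.17; without any 1 control FARSA, EPRS and YARS lost their calls (adjusted p up to 0.211, 0.154 and 0.105). The same 3 lost them with the GC and length trend removed (FARSA 0.428, EPRS 0.229, YARS 0.0608), and FARSA with library totals alone (0.634). With no low-count filter FARSA (0.173) and EPRS (0.0561) lost theirs, and EPRS with upper-quartile scaling (0.0634). On the deposited FPKM values HLA-C, COL17A1 and FARSA did not pass in any of the 3 settings (adjusted p 0.0509 to 0.841), and COL16A1, PSMA4, PSMD4 and PSMD1 did not with log2(FPKM + 1) and no filter (0.0575 to 0.0648). EPRS also lost its call without BCLAF1-depleted replicate 2 (0.0711) and FARSA without replicates 2 (0.0586) and 3 (0.0581).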
